A study of Mus musculus with 44 samples.

How the data were processed

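Polyadenylated RNA of 44 cultures of mouse CD4 T cells was sequenced as strand-marked libraries with paired reads of 150 bp, per the labels' protocols. The cells were naive CD4 T cells sorted from the spleens of C57BL/6NTac mice, plated at 150000 cells per well and cultured for 3 days. The deposited count table holds whole-number counts per gene, 1 column per library and sequencing lane, for 55416 genes, of which 1492 have no gene name. Per the file headers, reads were trimmed, aligned with STAR and sorted by coordinate before the authors counted them. The counting tool, the annotation, the strand setting, the treatment of reads that map to several genes and the versions are not given in the sources used here. The submitters' processing notes name the human assembly GRCh38, while the gene identifiers in the table are those of mouse. The authors also deposited a normalised table in CPM, whose columns have equal sums. Of its 88 columns, 79 gave whole reads for all values within 0.1 read. The other 9 hold 52345 to 55376 genes at 0, against at most 36715 in the intact ones, and were not used.

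The 2 lane columns of each library were summed. Lane totals differed by 3.59 to 3.93 times, and lanes of a library correlated at 0.997 or more. Library totals ran from 60815821 to 137415965 counts, and a floor of 3 counts was used where a gene was near 0. Groups were taken from the labels, 3 cultures by 3 genotypes. No 2 libraries of a group were copies: over 86 pairs the lowest median chi-square per gene was 6.72, where copies would give 0.455.

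Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, its default filter on low counts by group (21873 genes kept), a single model of 9 group means and the quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The 15 contrasts were set before the data were examined, namely Th1 and Treg against Th0 in WT, the 3 genotype pairs in each culture, and the differences of KO or KI effects between cultures. Levels are means ± SD of CPM with TMM factors, and fold changes are given with their SE on the log2 scale.

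In all 23 lists were fixed before the data were examined. They were the Th1, Treg, Th2 and Th17 programmes, the TGF-beta response, naive and quiescence genes, activation and inhibitory receptors, cytokines and receptors linked to EAE, reported miR-150 targets, interferon-stimulated genes, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, apoptosis, adhesion and migration, markers of B cells, of CD8 T and NK cells, of myeloid and dendritic cells and of erythroid cells, stress and dissociation genes, mitochondrial transcripts and sex-linked genes. Some genes stand in more than 1 list. Rows of the count table that share a gene name were counted separately, so a list can count more rows than it has genes, as glycolysis does. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 345 tests, and again with an estimated correlation and with fry.

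Genes were named by a rule fixed before the data were examined. It takes Mir150, its neighbours, Tbx21, Ifng, Foxp3 and Myb always. It then takes called genes with a mean log2 CPM of at least 2 and no overlap between the compared libraries, by largest fold change: 10 each way for culture effects, 8 for KO or KI against WT, 5 for KI against KO and 4 for differences of effects. From each list it takes up to 4 called members by size of change. Predicted genes were left out of the text.

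Seed matches were searched in 3' UTRs derived from the stop codons and exons of GENCODE release 21 on GRCm38. Of the genes tested, 66.4% had one, and 98.5% of those that code for protein. Genes with TTGGGAG (7mer-m8), which includes TTGGGAGA (8mer), were set against genes without it, weighted over 10 bins of 3' UTR length and 5 of expression. The difference between groups was tested by exact permutation of the libraries, two-sided, with Benjamini-Hochberg adjustment over the 6 results.

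Same-numbered libraries of a genotype were checked for pairing by the correlation of their deviations from the group means. It lay between 0.245 and 0.422 for Th0 with Th1 in WT, 0.185 and 0.494 in KO and 0.147 and 0.552 in KI, so these were read as pairs. The labels give the numbers but not their meaning.

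Both tests were tried on simulated data with the real means, library sizes and 200 changed genes of 21873. The changed genes had a mean log2 CPM of at least 2, so recovery of lower genes was not tried. Counts were drawn independently with the spread that edgeR had estimated, which may favour edgeR and leaves out any structure shared between libraries. In simulations of Th1 against Th0 in WT, edgeR recovered 22, 44, 49 and 50 of 50 genes changed by 1.5, 2, 4 and 8 times, with 9 false calls. For KO against WT in Treg it recovered 24, 44, 49 and 50, with 8 false calls, and for KI against WT in Th0 21, 41, 46 and 50, with 7. DESeq2 made 26, 23 and 32 false calls in these 3 simulations and recovered 25, 28 and 30 of the 50 genes changed by 1.5 times. A simulated shift of 0.1 in the seed-site genes came back as 0.0978.

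Alternatives set before the data were examined were RLE size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, a fit of the compared groups only, the library number as a block, and leaving out each library in turn. For seed sites they were 8mers only, 7mer-A1 matches added and unweighted control genes. Chosen after seeing the data were reads recovered from the normalised table, leaving out the libraries numbered WT 4, KO 2 and KI 3 (those with the highest mean Cd8a level of their genotype), a term for the sex of the animals, and a term for the Cd8a level. Antisense genes and genes with near-identical copies are uncertain, since the counting settings are not given in the sources used here. Text tables and plots were made with Python 3.11.15.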

Results

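Bulk mRNA was profiled from mouse CD4 T cells of 3 genotypes at the locus of microRNA-150 (miR-150), a short regulatory RNA of lymphocytes. The genotypes were wild type (WT), knockout (KO) and knock-in (KI). Naive CD4 T cells were sorted from spleen and cultured for 3 days with antibodies to CD3 and CD28. Cultures with these antibodies alone are called Th0, those with interleukin-12 and an antibody to interleukin-4 Th1, and those with TGF-beta 1 and an antibody to interferon-gamma Treg. The series title names experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis, and the differentiation and function of CD4 T cells. Each of the 9 groups held 5 libraries, except Th0 KI with 4, for 44 libraries in all. Libraries are named by culture, genotype and number (Treg WT 4). Total counts per library ran from 60815821 to 137415965, and 21873 of 55416 genes were tested. P-values for single genes, by fry and by permutation measure the spread between these libraries, since the labels do not say what a number marks. Camera sets the genes of a list against the other genes, so with its preset correlation its p-values do not measure that spread. Coordinates are those of the GRCm38 assembly in GENCODE release 21.

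The targeted gene itself was close to undetectable in these libraries, which were made from poly(A) RNA and do not measure the mature microRNA. Mir150 (ENSMUSG00000065495.1) is a hairpin gene at chromosome 7, 45121757 to 45121821, plus strand. It received 6 counts in total over the 15 WT libraries, 0 over the 15 KO libraries and 7 over the 14 KI libraries. No library held more than 2 counts, below the floor of 3 counts, which stood at 0.0218 to 0.0493 counts per 1000000 (CPM) by library and covers counting error only. Knock-in and wild type could not be told apart by these counts at this depth. The closest annotated transcript was Gm45552, an antisense gene at 45121917 to 45124144 on the plus strand, 96 bp from the hairpin. Gm45552 stood at 0.598 ± 0.244 CPM (SD, n = 5) in Th0 WT and 2.19 ± 1.67 CPM (SD, n = 5) in Treg WT. Its log2 fold change between these groups was 1.86 ± 0.42 (SE), with an adjusted p of 7.62e-04 by edgeR's quasi-likelihood test. Its value is uncertain, as the strand setting of the counting is not given in the sources used here. Between genotypes Gm45552 differed by 0.15 to 0.18 on the log2 scale for KO against WT in Th0 and Th1 and -0.09 in Treg. For KI against WT it differed by -0.20, 0.16 and 0.11 in Th0, Th1 and Treg, and for KI against KO by -0.35, -0.02 and 0.20. None of these passed the threshold.

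What the Th1 condition did to wild-type cells was read from Th1 WT against Th0 WT. Both subunit genes of the interleukin-18 receptor were higher in Th1 cultures, and Gata3 was lower. Il18r1, a subunit of the interleukin-18 receptor, had a log2 fold change of 3.61 ± 0.42 (SE), and its partner Il18rap one of 2.05 ± 0.22. The transcription factor gene Hlx was higher by 4.15 ± 1.11. Gata3 (chromosome 2, 9857078 to 9890034, minus strand), the master regulator of Th2 cells, fell from 47.9 ± 42.3 CPM to 2.96 ± 1.69 CPM (SD, n = 5 each), a log2 fold change of -4.02 ± 0.44.

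Of all genes tested, 486 were higher and 179 lower in Th1 WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Timp1, an inhibitor of metalloproteinases, rose most among the named genes, by 6.81 ± 1.11 on the log2 scale, followed by Sema3b at 5.26, the calcium pump gene Atp2b4 at 4.08 and the cholesterol exporter gene Abca1 at 3.64. Etv5, Slc4a11 and Stom rose by 3.61, 3.58 and 3.21. The Th2-linked chemokine receptor gene Ccr8 changed by -3.14 ± 0.51, the purinergic receptor gene P2ry1 by -2.97, Lad1 by -2.87 and the integrin gene Itgb3 by -2.48. Tspan2, Sema4b and Pter changed by -1.90, -1.75 and -1.49. Both genes most often used to define Th1 cells missed the threshold in this fit and passed when same-numbered libraries were paired. Ifng (chromosome 10, 118441046 to 118445892, plus strand) stood at 478 ± 681 CPM in Th0 WT and 1787 ± 773 CPM in Th1 WT (SD, n = 5 each), with an adjusted p of 0.567 by edgeR, and when paired a log2 fold change of 3.09 with an adjusted p of 0.0228 by edgeR. Th0 WT 4 held 1660.5 CPM of Ifng, against a mean of 183 CPM in the other Th0 WT libraries. Without Th0 WT 4 the unpaired log2 fold change of Ifng went from 1.90 to 3.30 and still did not pass. Tbx21, which encodes T-bet, had a log2 fold change of 0.45 ± 0.76 and an adjusted p of 0.847 by edgeR, and when paired 0.45 with an adjusted p of 0.0435 by edgeR.

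Of 24 measured genes of the Th1 programme list, 4 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 1.18e-04 by camera, and adjusted p = 0.937 with an estimated correlation). In the Th2 programme 1 rose and 3 fell of 13, 2 and 6 adjusted over the list alone. Il13, a Th2 cytokine gene, changed by -5.58 ± 1.59 and Il1rl1, the interleukin-33 receptor gene, rose by 2.32 ± 0.60. The Th2 list had adjusted p = 0.0246 by camera, and adjusted p = 0.981 with an estimated correlation. In the Treg programme 3 rose and 2 fell of 24, among them Il2ra at 1.17 and Lrrc32, which anchors latent TGF-beta, at -1.60. Of 17 reported miR-150 targets 3 rose, namely P2rx7 by 2.35, Zeb1 by 0.88 and Elk1 by 0.59. Myb, another of these reported targets, had a log2 fold change of 0.59 ± 0.23 and did not pass. Csf2, which encodes the cytokine GM-CSF linked to EAE, changed by -3.68 ± 0.89, and Il23r rose by 4.12 ± 0.99.

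The count of 665 genes became 1495 when same-numbered libraries were paired (832 higher and 663 lower), 195 when only these 10 libraries were fitted and 1031 with the Cd8a level as a term. It was 361 without Th1 WT 3, 408 without Th1 WT 4, 426 without Th1 WT 1 and 1296 without Th1 WT 5.

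The Treg condition changed the transcriptome of wild-type cells far more widely. Foxp3 (chromosome X, 7573644 to 7595245, plus strand), the lineage factor of regulatory T cells, stood at 1.81 ± 0.865 CPM in Th0 WT and 371 ± 249 CPM in Treg WT (SD, n = 5 each), a log2 fold change of 7.69 ± 0.69 (SE). Some genes that respond to TGF-beta rose with it, such as Itgae, which encodes the integrin CD103, by 6.31 ± 0.63, and Ldlrad4 by 6.38 ± 0.55. Nt5e, the ectoenzyme CD73, rose by 6.32 ± 0.65. Il2, the growth factor that activated T cells secrete, went the other way, from 237 ± 66.3 CPM to 1.02 ± 0.339 CPM (SD, n = 5 each).

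In all, 3807 genes were higher and 3440 lower in Treg WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of 21873 tested. The transcription factor genes Maf and Tead1 rose by 6.40 and 6.20 on the log2 scale, the inhibitory surface protein gene Cd101 by 6.16, Nav1 by 5.52, Igfbp4 by 4.87 and Acsbg1 by 4.75. Il2 changed by -7.84 ± 1.17, Csf2 by -5.47 ± 0.97, the immunoglobulin gene Ighg1 by -4.61 and the chemokine gene Ccl3 by -3.05. Ptpn5, Ccn4, Dclk1, Serpinb9 and Cth changed by -3.48, -3.42, -3.20, -3.12 and -3.01. Myb rose by 0.80 ± 0.23. Ifng and Tbx21 had log2 fold changes of -1.37 ± 1.35 and -1.73 ± 0.78 and did not pass. Both passed without Treg WT 4, at -4.55 and -2.69, with the Cd8a level as a term, at -4.25 and -2.99, and without the libraries numbered WT 4, KO 2 and KI 3, at -3.14 and -2.63. With the library number as a block both also passed, at -4.69 and -3.69 (adjusted p = 0.0225 and 0.0483 by edgeR). Whether the numbers pair Th0 with Treg libraries is uncertain. In WT same-number libraries correlated at 0.221 on average (lowest 0.0919), against -0.0551 for other numbers. Of 5 Th0 WT libraries 4 correlated best with their own number. The main fit leaves out any such pairing, and with the number as a block 5352 genes were called. Without Th0 WT 4 the value for Ifng was 0.03. The total was 4478 genes when only these 10 libraries were fitted.

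Gene lists are given next as the numbers that rose and fell over all genes tested, with those adjusted over the list alone in parentheses. In the Treg programme 14 rose and 3 fell of 24 (14 and 4), and Lrrc32 rose by 3.91. In the TGF-beta response 10 rose and 1 fell of 14 (10 and 1), with Tgfbr1 at 3.54 and Pmepa1 at 2.51. In the Th1 programme 2 rose and 8 fell of 24 (2 and 8), with Ccl4 at -2.56, Ccl5 at -2.29 and Il18r1 at 3.79. In the Th2 programme 1 rose and 2 fell of 13 (1 and 2), and the riser was Maf. In the Th17 programme 6 rose and 2 fell of 14 (6 and 3), with Il17f at 3.97 and Il22 at -5.69. Of the naive and quiescence genes 15 rose and 1 fell of 22 (16 and 1), led by Klf2 at 5.51, which keeps T cells quiescent, and S1pr1 at 2.85. Of the activation and inhibitory receptor genes 1 rose and 10 fell of 20 (1 and 11), with Nr4a2 at -2.00 and Cd69 at -1.64. Of the cytokines and receptors linked to EAE 5 rose and 5 fell of 16 (5 and 5), with Il3 at -5.81 and Il6ra at 2.99. Of the reported miR-150 targets 8 rose and 1 fell of 17 (8 and 1), with Ccr6 at 2.76, Cxcr4 at 2.03 and Foxo1 at 1.42.

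Of the interferon-stimulated genes 0 rose and 9 fell of 22 (0 and 9), with the chemokine gene Cxcl10 at -4.41 and the antiviral gene Mx1 at -3.41. In glycolysis 0 rose and 8 fell of 19 measured rows (0 and 9), with the hexokinase gene Hk2 at -1.40 and the lactate transporter gene Slc16a1 at -1.18. In oxidative phosphorylation 0 rose and 10 fell of 20 (0 and 12), with cytochrome c, Cycs, at -0.94. In cholesterol synthesis 1 rose and 2 fell of 18 (1 and 2), in the cell cycle list 2 rose and 4 fell of 22 (2 and 3), and in apoptosis 3 rose and 9 fell of 17 (3 and 9), with Bcl2l1 at -1.44. Of the adhesion and migration genes 7 rose and 3 fell of 18 (7 and 3), with Itga6 at 1.99. Of the stress and dissociation genes 1 rose and 5 fell of 12 (1 and 6), with the heat shock gene Hsp90aa1 at -1.05. None of the 10 mitochondrial transcripts and none of the 5 sex-linked genes passed. Without the libraries numbered WT 4, KO 2 and KI 3, more genes fell over all genes tested: 14 in the Th1 programme, 14 in glycolysis, 9 in the cell cycle list, 5 in cholesterol synthesis, 5 in the Treg programme, 5 in the Th17 programme, 4 in the Th2 programme and 2 of the naive and quiescence genes. In that fit 0 activation and inhibitory receptor genes and 1 interferon-stimulated gene rose. Over all 23 lists the adjusted p by camera with an estimated correlation ran from 0.0631 to 0.991 in this comparison, so no list call held under it. The same was true of all 82 list calls that camera made over the 15 comparisons with its preset correlation.

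Markers of other cells moved as well. Of the myeloid and dendritic cell markers 4 rose and 0 fell of 13 (4 and 0), with Itgam at 3.84 and Lyz2 at 2.92. S100a8, abundant in neutrophils, was below the floor in Th0 WT and at 1.61 ± 1.06 CPM (SD, n = 5) in Treg WT. Of the B cell markers 0 rose and 1 fell of 10 (0 and 0), namely Igkc at -2.35 (0 without the libraries numbered WT 4, KO 2 and KI 3), and of the CD8 T and NK cell markers 1 rose and 0 fell of 8 (0 and 0), namely Klrd1 at 2.65. No erythroid marker of 6 passed, and 1 fell in the same fit without these libraries. Foxp3 spread widely among the wild-type Treg libraries, from 47.7 CPM in Treg WT 4 to 596 CPM in Treg WT 5. Cd8a, a marker of CD8 T cells that the CD4 sort should remove, stood at 443 CPM in Treg WT 4 and at 23.9 CPM or less in the other 4.

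**Figure D1:**
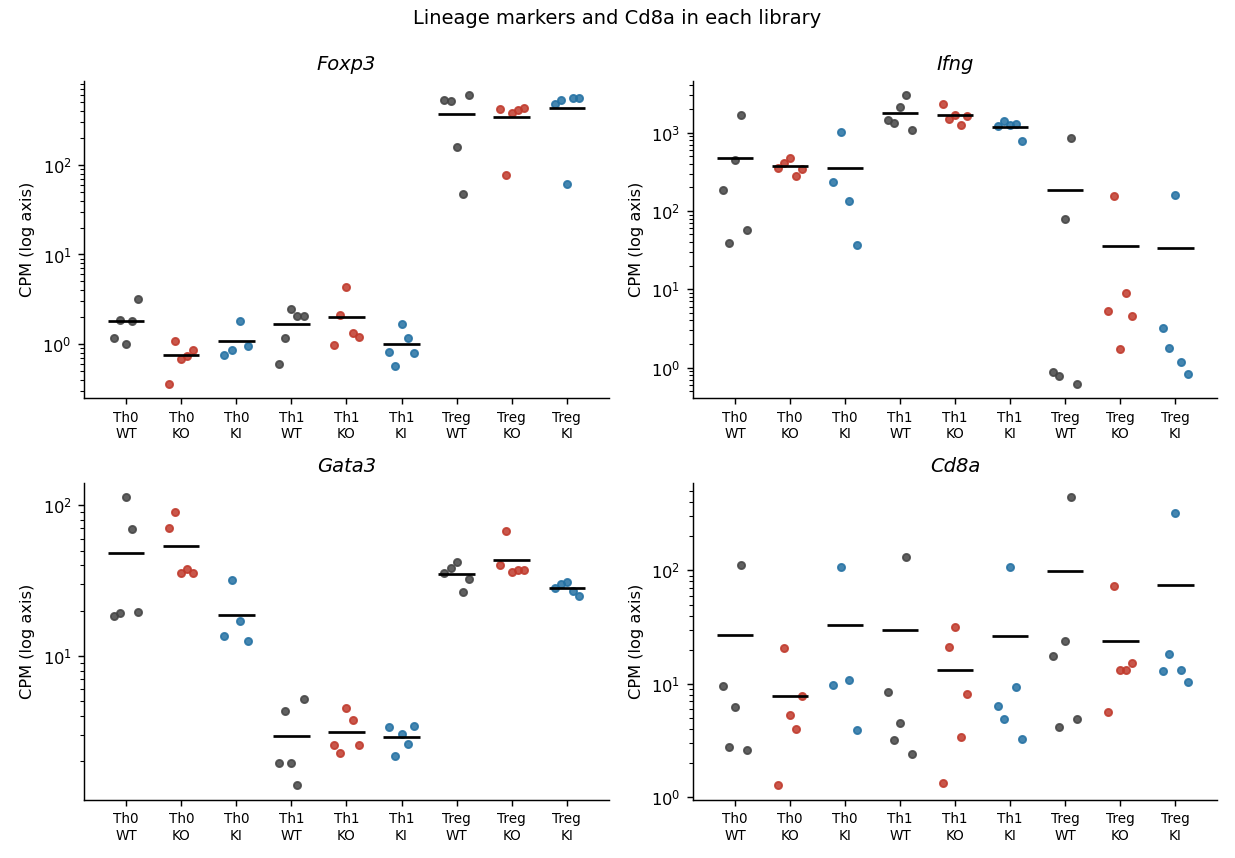
Levels of Foxp3, Ifng, Gata3 and Cd8a in each of the 44 libraries, in CPM on log axes, by culture and genotype. Each point is a library and each line a group mean. Foxp3 lies above 47 CPM in all 15 Treg libraries and below 4.35 CPM in all Th0 and Th1 libraries.

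The effect of losing miR-150 was read from KO against WT within each culture. In Treg cultures, Myb and some interferon-induced genes were called higher in KO, although chance could not be excluded for the number of genes called, as set out below. Myb (chromosome 10, 21124935 to 21160984, minus strand), a transcription factor gene and a reported target of miR-150, stood at 94.2 ± 20.6 CPM in WT and 202 ± 78.6 CPM in KO (SD, n = 5 each), a log2 fold change of 1.10 ± 0.24 (SE). The guanylate-binding protein genes Gbp5, Gbp7 and Gbp3, induced by interferon-gamma, were higher by 1.58 ± 0.31, 1.54 ± 0.32 and 1.43 ± 0.25. Gbp5 (chromosome 3, 142493978 to 142522344, plus strand) stood at 101.96 ± 39.4 CPM in WT and 305 ± 90.6 CPM in KO. Nol4l (chromosome 2, 153407462 to 153529971, minus strand) was lower, at 12.6 ± 6.16 CPM in WT and 3.67 ± 0.714 CPM in KO, a log2 fold change of -1.78 ± 0.27.

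In total 23 genes were higher and 14 lower in KO Treg cultures by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The peptide transporter gene Tap1 rose by 0.96 ± 0.21, the class I gene H2-Q4, which has near-identical copies and is uncertain, by 0.74, the pyruvate dehydrogenase kinase gene Pdk1 by 0.84 ± 0.15, Pgp by 0.67 and Desi1 by 0.49. The phosphate transporter gene Slc20a1 fell, at -0.56 ± 0.11. Of 22 interferon-stimulated genes 2 rose, and 14 rose adjusted over the list alone, with a median log2 fold change of 0.97 (adjusted p = 2.87e-23 by camera, and adjusted p = 0.0836 with an estimated correlation). By fry, which asks if the genes moved one way on balance, the list had an adjusted p of 0.00388. Of 19 measured rows of glycolysis genes 1 rose and 2 rose adjusted over the list alone (adjusted p = 9.67e-14 by camera, and adjusted p = 0.584 with an estimated correlation). No cholesterol synthesis gene of 18 passed, although the list had adjusted p = 2.14e-10 by camera, and adjusted p = 0.641 with an estimated correlation. Th17 programme genes had a median of -0.81, with adjusted p = 0.0121 by camera, and adjusted p = 0.584 with an estimated correlation. Mitochondrial transcripts, a measure of RNA quality, had a median of -0.32 (adjusted p = 4.29e-04 by camera, and adjusted p = 0.974 with an estimated correlation). Foxp3 stood at 343 ± 149.9 CPM in KO (SD, n = 5), with a log2 fold change of -0.11 ± 0.51. Ifng had a log2 fold change of -2.38 ± 1.39 and did not pass. Its sign is uncertain, as the value ran from -5.19 to 0.96 over the fits. Treg WT 4 held 846 CPM of Ifng, against a mean of 20.2 CPM in the other Treg WT libraries. Without the libraries numbered WT 4, KO 2 and KI 3, more list genes moved: 4 interferon-stimulated genes rose over all genes, and 12 glycolysis and 4 cholesterol synthesis genes rose and 6 Th17 programme genes fell adjusted over the list alone. The medians there were 0.74 for glycolysis (adjusted p = 0.0401 by fry, 0.107 with all libraries) and -1.17 for the Th17 programme (adjusted p = 0.0189 by fry, 0.163 with all libraries).

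The 37 genes became 164 by DESeq2, 66 of them higher and 98 lower. DESeq2 made 23 false calls on simulated data of this comparison where edgeR made 8. As the simulation used edgeR's own estimates of spread, it cannot tell which method is closer on the real libraries. The main method called 0 when only these 10 libraries were fitted, and 229 without the libraries numbered WT 4, KO 2 and KI 3, which had the highest mean Cd8a of their genotypes, 79 higher and 150 lower. Without Treg WT 4 alone 31 were higher and 59 lower, so which direction held more genes depended on the method and the libraries. Per 1000 genes tested, 1.69 were called, 5.85 with the Cd8a level as a term and 6.04 without Treg KO 2. The count was 2 without Treg WT 5, 10 without Treg KO 4 or Treg KO 5, 12 without Treg KO 1, 14 without Treg KO 3, 16 without Treg WT 2, 90 without Treg WT 4 and 194 without Treg WT 3.

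**Figure D2:**
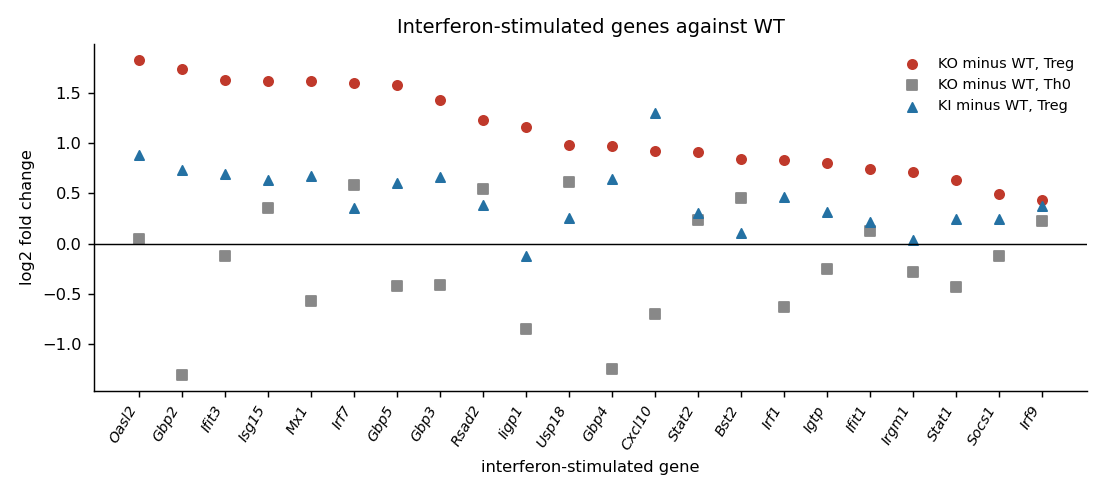
Log2 fold changes of the 22 measured interferon-stimulated genes for KO minus WT in Treg cultures, KO minus WT in Th0 cultures and KI minus WT in Treg cultures. Each point is a gene, without error bars. The median is 0.97 in KO Treg cultures.

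In Th0 and Th1 cultures no gene separated KO from WT. edgeR called 0 genes in Th0, with 1048 at an unadjusted p under 0.05, where DESeq2 called 3, and 0 in Th1, with 2000 at an unadjusted p under 0.05, where DESeq2 called 19. The Th1 count was 1 without Th1 WT 1 and 3 without Th1 WT 3. Myb stood at 54.2 ± 14.5 CPM in Th0 WT and 66.5 ± 8.07 CPM in Th0 KO, and at 81.6 ± 31.9 CPM in Th1 WT and 129.97 ± 13.1 CPM in Th1 KO (SD, n = 5 each). Its log2 fold changes were 0.29 ± 0.23 and 0.67 ± 0.23. The B cell markers had medians of -1.10 in Th0 and -1.09 in Th1, with none of 10 past the threshold in either (adjusted p = 6.46e-04 by camera, and adjusted p = 0.981 with an estimated correlation in Th0; adjusted p = 2.94e-04 by camera, and adjusted p = 0.974 with an estimated correlation in Th1). The Th0 median was -0.72 without the libraries numbered WT 4, KO 2 and KI 3. Cell cycle genes had medians of -0.12 and -0.32, again with none past the threshold (adjusted p = 2.58e-09 by camera, and adjusted p = 0.651 with an estimated correlation in Th1), and 10 were lower in Th1 adjusted over the list alone without the libraries numbered WT 4, KO 2 and KI 3. Mitochondrial transcripts had medians of -0.35 in Th0 and -0.20 in Th1.

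**Figure D3:**
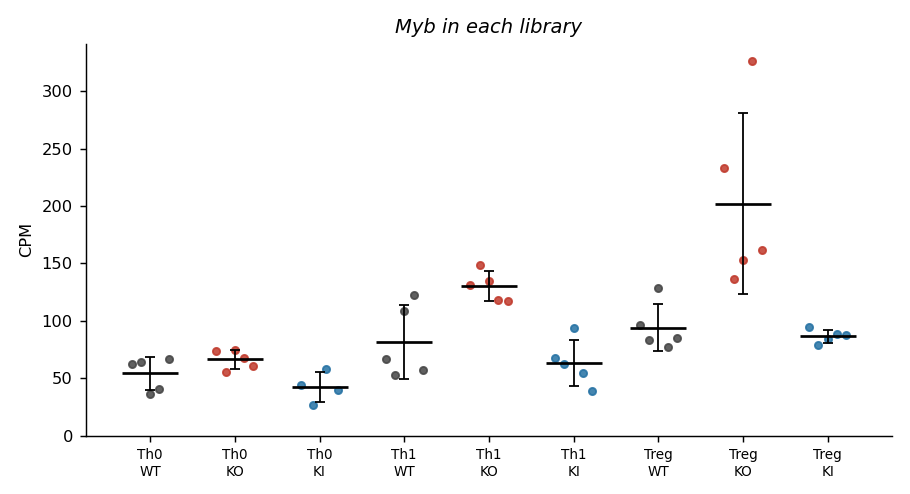
Myb in CPM (linear axis from 0) in each of the 44 libraries, by culture and genotype. Points are libraries, and bars the mean ± SD of the group. Mean Myb is highest in KO in each culture, at 66.5, 129.97 and 202 CPM in Th0, Th1 and Treg.

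The knock-in was compared with the wild type in the same way. In Th0 cultures, F2r (chromosome 13, 95601803 to 95618487, minus strand), which encodes the thrombin receptor PAR1, stood at 33.4 ± 8.21 CPM in WT (SD, n = 5) and 14.4 ± 0.895 CPM in KI (SD, n = 4), a log2 fold change of -1.21 ± 0.23 (SE). Colq, which anchors acetylcholinesterase, was higher by 1.36 ± 0.25, the antiviral gene Oas1c by 1.30 ± 0.28 and the lysosomal protease gene Ctss by 1.22 ± 0.28. In Th1 cultures F2r was again lower, at -1.32 ± 0.22, and Colq higher, by 1.25 ± 0.24.

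By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5.12 of every 1000 genes tested were called in Th0 KI, all but 9 of them higher. Ccdc173 and Hint3 were among them, at 1.11 and 0.94. Of 83 ribosomal protein genes 11 were called higher, a group chosen after its values were seen. The libraries disagreed: the median log2 difference of the 83 from the Th0 WT mean was 0.92 in Th0 KI 1, 0.67 in Th0 KI 3, -0.07 in Th0 KI 4 and 0.21 in Th0 KI 5. Myb stood at 42.25 ± 13.04 CPM in Th0 KI (SD, n = 4), with a log2 fold change of -0.36 ± 0.25 that did not pass. No list member of the 23 lists passed over all genes in Th0 KI. Interferon-stimulated genes had a median of 0.81, 2 of 22 past the threshold adjusted over the list alone (adjusted p = 2.71e-04 by camera, and adjusted p = 0.974 with an estimated correlation). Cell cycle genes had a median of -0.30, 3 of 22 lower adjusted over the list alone (adjusted p = 1.46e-06 by camera, and adjusted p = 0.857 with an estimated correlation), and 0 without the libraries numbered WT 4, KO 2 and KI 3, where the median was -0.20. The total of called genes became 659 by DESeq2, 181 of them lower. DESeq2 made 32 false calls on data simulated with edgeR's estimates of spread for this comparison, against 7 by edgeR. The total was 22 with the other size factors, 4 with no filter on low counts, 254 with a stricter one and 0 when only these 9 libraries were fitted. It was 54 with a Cd8a term and 1 without the libraries numbered WT 4, KO 2 and KI 3. The count was 0 without Th0 KI 1 or Th0 KI 3, 1 without Th0 WT 4, 2 without Th0 WT 2 or Th0 WT 3, 7 without Th0 WT 5, 287 without Th0 KI 5, 531 without Th0 WT 1 and 974 without Th0 KI 4.

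In Th1 KI 2 genes were higher and 4 lower. F2r stood at 23.3 ± 8.76 CPM in WT and 9.30 ± 1.63 CPM in KI (SD, n = 5 each). Outside the rule for named genes, and chosen after their values were seen, Nectin3 changed by -2.86, Gprin3 by -1.31, Them4 by -1.26 and Acap2 by 0.64. No cell cycle gene passed over all genes, and 19 of 22 were lower adjusted over the list alone, with a median of -0.48 (adjusted p = 1.47e-18 by camera, and adjusted p = 0.338 with an estimated correlation; adjusted p = 0.0118 by fry). Without the libraries numbered WT 4, KO 2 and KI 3, 12 were lower, with a median of -0.34 (adjusted p = 0.0487 by fry). Myb had a log2 fold change of -0.36 ± 0.23. The 6 genes became 458 by DESeq2, 0 when only these 10 libraries were fitted, 10 on reads recovered from the normalised table, and 2 without the libraries numbered WT 4, KO 2 and KI 3. The count was 1 without Th1 KI 1, Th1 KI 2, Th1 KI 3, Th1 WT 2 or Th1 WT 5, 2 without Th1 KI 5, 3 without Th1 WT 4, 18 without Th1 WT 1 and 313 without Th1 KI 4.

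In Treg cultures edgeR called 0 genes between KI and WT, with 1758 at an unadjusted p under 0.05, and DESeq2 called 12. The edgeR count was 2 without Treg WT 1. Foxp3 stood at 437 ± 212 CPM in KI (SD, n = 5), a log2 fold change of 0.23 ± 0.51, and Myb differed by -0.12 ± 0.23. B cell markers, which a CD4 sort should remove, had a median of 1.72 with none past the threshold (adjusted p = 7.19e-06 by camera, and adjusted p = 0.811 with an estimated correlation). Interferon-stimulated genes had a median of 0.38 (adjusted p = 8.44e-06 by camera, and adjusted p = 0.821 with an estimated correlation). These medians were 0.87 and 0.25 without the libraries numbered WT 4, KO 2 and KI 3.

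Knock-in and knockout were also compared directly. In Treg cultures Myb was lower in KI, with a log2 fold change of -1.22 ± 0.24 (SE), Nol4l was higher by 1.40 ± 0.27 and the phosphatase gene Ppm1l was lower, at -0.99 ± 0.19. These were 3 of 5 genes called by edgeR. The other 2, Aqp11 at -2.04 and Adamts20 at -6.99, were named after their values were seen. In Th0 and Th1 edgeR called 0 genes, with 2684 and 1296 at an unadjusted p under 0.05, while DESeq2 called 140 and 42. Myb had log2 fold changes of -0.65 ± 0.25 in Th0 and -1.03 ± 0.24 in Th1, where it passed by DESeq2 (adjusted p = 0.0231). B cell markers were the list with the highest median, 2.13, 1.85 and 2.11 in Th0, Th1 and Treg, with 7, 2 and 8 of 10 higher adjusted over the list alone and none over all genes (adjusted p = 7.98e-08 by camera, and adjusted p = 0.641 with an estimated correlation in Treg). Without the libraries numbered WT 4, KO 2 and KI 3 the medians were 1.41, 1.52 and 1.58, and 0 of these genes passed in any culture. Cd79a stood at 6.40 ± 5.63 CPM in Treg KO and 25.79 ± 16.97 CPM in Treg KI (SD, n = 5 each). Interferon-stimulated genes had a median of -0.73 in Treg (adjusted p = 1.64e-09 by camera, and adjusted p = 0.603 with an estimated correlation) and 0.79 in Th0 (adjusted p = 3.34e-08 by camera, and adjusted p = 0.641 with an estimated correlation). Without the libraries numbered WT 4, KO 2 and KI 3 the Treg median was -1.08, with 8 of 22 lower adjusted over the list alone, against 2 with all libraries (adjusted p = 0.0439 by fry, 0.277 with all libraries).

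The Treg count of 5 became 59 by DESeq2, 18 with a Cd8a term and 13 without the libraries numbered WT 4, KO 2 and KI 3. When only these 10 libraries were fitted the count was 3, with 0 of the 5 genes among them. On recovered reads the count was 3, with 2 of the 5 among them. It was 0 without Treg KI 3, Treg KI 4, Treg KO 1 or Treg KO 3, 1 without Treg KI 2 or Treg KO 4 and 3 without Treg KI 5. In Th0 the count was 8 with a Cd8a term, 1 with the sex of the animals as a term, and 1 without Th0 KI 1, Th0 KI 5, Th0 KO 4 or Th0 KO 5 and 292 without Th0 KI 4.

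Whether a genotype effect differed between cultures was tested directly. edgeR called 0 genes for each of the 4 differences. For the KO effect 384 genes in Th1 against Th0 and 1149 in Treg against Th0 had an unadjusted p under 0.05, and for the KI effect 712 and 1360. DESeq2 called 3, 19, 1 and 4. For the KO effect in Treg against Th0 the count was 10 without the libraries numbered WT 4, KO 2 and KI 3, and 1 without Treg WT 1, 3 without Th0 WT 3 or Treg KO 2 and 13 without Treg WT 3. Interferon-stimulated genes had a median difference of 1.17 between the KO effects in Treg and Th0, with 9 of 22 past the threshold adjusted over the list alone (adjusted p = 5.80e-22 by camera, and adjusted p = 0.0912 with an estimated correlation; adjusted p = 0.0408 by fry). The KO effect on Myb differed by 0.81 ± 0.33 between Treg and Th0 and by 0.38 ± 0.33 between Th1 and Th0, neither past the threshold.

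Messenger RNAs with a match to the miR-150-5p seed in the 3' UTR were compared as a group. The mature sequence UCUCCCAACCCUUGUACCAGUG pairs through its seed with TTGGGAG, found in the annotated 3' UTR of 2324 of 14523 genes. The mean log2 level of these genes, relative to 12199 genes without a match and of like 3' UTR length and expression, differed between KO and WT by 0.0197 in Th0, 0.0103 in Th1 and 0.0393 in Treg. The exact two-sided permutation p-values were 0.159, 0.579 and 0.103. For KI minus WT the differences were 0.0405, 0.0183 and 0.0274, with exact permutation p-values of 0.0317, 0.262 and 0.214. None of the 6 passed Benjamini-Hochberg adjustment, the lowest exact permutation adjusted p being 0.190 for KI in Th0. With unweighted control genes the sign turned in 5 of the 6, all but KO in Th0. With 8mer matches only the difference was 0.0186 for KO in Treg and 0.0167 for KO in Th1. With 7mer-A1 matches added it was 0.0330, 0.0279, 0.0388 and 0.0420 for KO in Th0, KO in Th1, KI in Th1 and KI in Treg.

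Other cell types and the sex of the animals were read from marker genes. Cd8a was highest in the libraries numbered WT 4 and KI 3, at 443 and 318 CPM in the Treg cultures, and stood at 73.1 CPM in Treg KO 2. Foxp3 was 61.97 CPM in Treg KI 3 and 77.4 CPM in Treg KO 2. Xist and Y-linked genes gave the same sex in all cultures for each of the 15 combinations of genotype and number, 3 males in WT, 2 in KO and 2 in KI. Mitochondrial transcripts took 2.3 to 5.3% of counts.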

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

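The tests of the Foxp3 spread and of transcripts of the other sex, and the fits without the libraries numbered WT 4, KO 2 and KI 3, were chosen after the results they concern were seen. A library was picked out when its gap to the nearest other library of its group, divided by the range of the group, passed Dixon's limit at the 95% level. Of 84 such comparisons 16 passed. Chance gives about 1 in 20 for independent, normally distributed values. These comparisons share libraries and numbers, and CPM was not log-transformed, so an excess over chance cannot be read from this count. Cd8a stood apart in 7 groups, at 112.7 CPM in Th0 WT 4, 131.5 CPM in Th1 WT 4, 443 CPM in Treg WT 4, 107.5 CPM in Th0 KI 3, 107.4 CPM in Th1 KI 3, 318 CPM in Treg KI 3 and 73.1 CPM in Treg KO 2. The nearest other library of these groups held 8.49 to 23.9 CPM. Ifng stood at 1660.5 CPM in Th0 WT 4 against a mean of 183 CPM in the other 4, and at 846 CPM in Treg WT 4 against 20.2 CPM. Foxp3 was low, at 77.4 CPM in Treg KO 2 and 61.97 CPM in Treg KI 3. Genes with any count numbered 21656 in Th0 WT 5 and 21850 in Th1 WT 5, the fewest of their groups, and 23650 in Treg KO 5, the most of its group. Mitochondrial transcripts took 3.83% of counts in Treg KO 3, the most of its group, and Gm45552 stood at 0.732 CPM in Th1 WT 2.

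Camera with its preset correlation also picked out 14 list differences, where the genotype effect on a list differed between cultures. Each is given as the median log2 difference of effects over the list, with camera's adjusted p. For the KO effect in Th1 against Th0 these were the Th1 programme at -0.35 (adjusted p = 0.0293) and cell cycle at -0.14 (adjusted p = 0.00364). For the KO effect in Treg against Th0 they were the TGF-beta response at -0.49 (adjusted p = 0.00253), the Th17 programme at -0.78 (adjusted p = 0.0148), cytokines and receptors linked to EAE at -0.68 (adjusted p = 0.0413) and interferon-stimulated genes at 1.17 (adjusted p = 5.80e-22). In the same contrast stood cell cycle at 0.25 (adjusted p = 1.18e-04), glycolysis at 0.46 (adjusted p = 5.49e-08) and cholesterol synthesis at 0.37 (adjusted p = 2.00e-07). For the KI effect in Th1 against Th0 they were the Th1 programme at -0.43 (adjusted p = 0.0325), naive and quiescence genes at 0.15 (adjusted p = 0.0423) and cell cycle at -0.19 (adjusted p = 0.00242). For the KI effect in Treg against Th0 they were cell cycle at 0.20 (adjusted p = 0.00303) and glycolysis at 0.34 (adjusted p = 0.00126). The Th17 programme stood at -0.26 and glycolysis at 0.78 for the KO effect in Treg against Th0 without the libraries numbered WT 4, KO 2 and KI 3. With an estimated correlation the adjusted p of these 14 ran from 0.0912 to 0.981, and by fry it was 0.0408 for the interferon-stimulated genes and 0.277 or more for the other 13.

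As a list, the 22 interferon-stimulated genes were higher in KO than in WT Treg cultures by camera with its preset correlation but not with an estimated one (adjusted p = 0.0836), with 2 called one by one over all genes and a mean log2 level of 5.86 ± 0.43 in KO and 4.44 ± 1.02 in WT (SD, n = 5 each). CD8 T cells in WT 4 and KO 2 are argued against as the cause. Without the libraries numbered WT 4, KO 2 and KI 3 the list's median log2 fold change was 1.21 (fry adjusted p = 0.00171). The mitochondrial share is argued against as the whole cause, since with it as a term the median was 0.839 (fry adjusted p = 0.0135). That term cannot settle RNA quality in general. Treg WT 2 and Treg WT 5 held 4.69 and 5.26% mitochondrial counts, against at most 3.83% in Treg KO, and other measures of RNA quality were not tested. Over all splits of the 10 libraries into equal groups, 3, the real one included, gave a mean difference as large, at 1.42 for the real split and 1.56 for the highest other (exact two-sided permutation p = 0.0238 for this list on its own). Adjusted for the choice of 1 list among 23, these splits are too few for a share under 0.05. What stays open includes the genotype, RNA quality beyond the mitochondrial share, and any difference in the housing, handling or culture day of the animals, which the sources used here do not give. Foxp3 and Ifng also differed widely between these Treg libraries, and whether the list followed them was not tested.

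Foxp3 ran from 47.7 to 596 CPM over the 15 Treg libraries, 12.5-fold, and within each genotype it was lowest in the library with the highest Cd8a. Dilution by CD8 T cells alone is argued against, since the ratio of Foxp3 to Cd4 still varied 7.33-fold, and Treg WT 3 held 159 CPM of Foxp3 with 23.9 CPM of Cd8a. A wrong culture label is argued against by the lowest Treg library, at 47.7 CPM, lying above the highest Th0 or Th1 library, at 4.35 CPM. Genotype is argued against as the whole cause, since Foxp3 varied 5.57-fold or more within each genotype. The cultures may differ in how many cells turned on Foxp3, which was not tested.

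Transcripts of the other sex appeared in 2 libraries. Th1 KO 3, from a female by its other transcripts, held 4 Y-linked genes at 5.39 to 7.48% of the mean of the male libraries of its culture. Treg WT 4, from a male, held Xist at 77.2 CPM, 2.86% of the mean of the female libraries of its culture. The other male libraries of all cultures held 0.662 CPM or less. Reads or RNA from a library of the other sex would need all 4 Y-linked genes in Th1 KO 3, and they were all there, but the range allowed was set after these values were seen, so the source stays open. Th0 KO 3 and Treg KO 3 held 0 CPM of the Y-linked gene Ddx3y, and Th0 WT 4 and Th1 WT 4 held 0.435 and 0.294 CPM of Xist. If a number marks an animal, which the labels do not say, these values argue against an origin in the animals. Whether this arose in the sort, the cultures or the libraries could not be read from these data, and no biological explanation was tested.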

How the results depend on the processing

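Chosen after the results were seen were the fits on recovered reads, without the libraries numbered WT 4, KO 2 and KI 3, with a sex term and with a Cd8a term, and the number of splits for comparisons with no gene called; the other alternatives were planned. Numbers of called genes are given as a rate, per 1000 of the 21873 genes tested in the main fit, also where an alternative tested another number (35621 with no filter on low counts, 11355 with a stricter one, 15084 to 21866 by DESeq2, 22554 on recovered reads), and stood at 30.4 for Th1 against Th0 in WT, 331 for Treg against Th0 in WT, 1.69 for KO in Treg, 5.12 for KI in Th0, 0.274 for KI in Th1 and 0.229 for KI against KO in Treg, and 0 for the other 9. KO and KI in a culture are against WT. In the 6 comparisons with calls, no called named gene turned its direction under any alternative or without any 1 library. Of 40 named genes called for Th1 against Th0 in WT, 23 stayed called under all alternatives that kept all libraries or left out the 3 numbers, and of 79 for Treg against Th0 in WT 55 did. Of the 12, 10, 2 and 3 named genes called for KO in Treg, KI in Th0, KI in Th1 and KI against KO in Treg, 0 did. A stricter filter removed some named genes, which have no value there.

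For KI in Th0 the rate was 1.01 with RLE size factors, 0.183 with no filter and 11.6 with a stricter filter. By DESeq2 it was 0.137 for KO in Th0 and KO effect in Th1 minus Th0, 0.869 for KO in Th1 and KO effect in Treg minus Th0, 7.498 for KO in Treg, 30.1 for KI in Th0, 20.9 for KI in Th1, 0.549 for KI in Treg, 6.40 for KI against KO in Th0, 1.92 for KI against KO in Th1, 2.70 for KI against KO in Treg, 0.0457 for KI effect in Th1 minus Th0 and 0.183 for KI effect in Treg minus Th0. When only the compared groups were fitted it was 8.92 for Th1 against Th0 in WT, 205 for Treg against Th0 in WT, 0 for KO in Treg, KI in Th0 and KI in Th1 and 0.137 for KI against KO in Treg. With the library number as a block it was 68.3 for Th1 against Th0 in WT and 0 for KO in Treg, KI in Th0, KI in Th1 and KI against KO in Treg. On reads recovered from the normalised table it was 0.457 for KI in Th1 and 0.137 for KI against KO in Treg. Without the libraries numbered WT 4, KO 2 and KI 3 it was 10.5 for KO in Treg, 0.0457 for KI in Th0, 0.0914 for KI in Th1, 0.594 for KI against KO in Treg and 0.457 for KO effect in Treg minus Th0. With the sex of the animals as a term it was 0.0457 for KI against KO in Th0. With the Cd8a level as a term it was 47.1 for Th1 against Th0 in WT, 5.85 for KO in Treg, 2.47 for KI in Th0, 0.366 for KI against KO in Th0 and 0.823 for KI against KO in Treg. The cause was not tested for these or for leaving out a library, except that fits of the compared groups alone have fewer libraries to estimate the spread. Numbers pair Th0 with Th1 libraries but not different genotypes. For Th0 with Treg in WT this is uncertain, with a mean same-number correlation of 0.221 and a lowest of 0.0919. With that block Ifng and Tbx21 passed for Treg against Th0 in WT, at -4.69 and -3.69. Leaving out 1 library, the rate ran from 16.5 to 59.2 for Th1 against Th0 in WT, 265 to 376 for Treg against Th0 in WT, 0 to 0.137 for KO in Th1, 0.0914 to 8.87 for KO in Treg, 0 to 44.5 for KI in Th0, 0.0457 to 14.3 for KI in Th1, 0 to 0.0914 for KI in Treg, 0 to 13.3 for KI against KO in Th0, 0 to 0.274 for KI against KO in Treg and 0 to 0.594 for KO effect in Treg minus Th0. Of 82 list calls by camera, 0 held with an estimated correlation and fry made 12.

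For the seed-site genes, judged on the unadjusted exact p, unweighted control genes turned the sign to -0.0191 for KO in Th1, -0.0239 for KO in Treg, -0.0423 for KI in Th0, -0.0204 for KI in Th1 and -0.0291 for KI in Treg, and the cause was not tested. For KI in Th0 the difference was 0.0477 with 7mer-A1 matches added (exact permutation p = 0.0635), 0.0366 with the number as a block (exact permutation p = 0.125, the smallest that test can give) and 0.0317 without the 3 numbers (exact permutation p = 0.114). For KI in Treg it was 0.0420 with 7mer-A1 matches added (exact permutation p = 0.0317). Leaving out 1 library, it ran from 0.0145 to 0.0293 for KO in Th0, 0.0294 to 0.0509 for KO in Treg and 0.0332 to 0.0483 for KI in Th0, with exact p on both sides of 0.05 in each, and from 0.00257 to 0.0198 for KO in Th1, 0.0106 to 0.0270 for KI in Th1 and 0.0176 to 0.0391 for KI in Treg, with exact p above it.

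Other splits of the same libraries were fitted, 100 per comparison with calls and 40 without. Taken alone, chance can be excluded for Treg against Th0 in WT. It had 7247 genes, and 6147 in the highest other split (1 of 100 as large). For KO in Treg chance cannot, with 37 and 2654 (16 of 100). KI against KO in Treg, with 5 and 2 (1 of 100), stays open, as its groups fitted alone called 0 of the 5. Over the 6, 100 splits are too few to adjust. The share was under 0.05 for KI in Th0, with 5.12 genes per 1000 in the real split and 445 genes in the highest other (4 of 100), and KI in Th1, with 6 and 193 (2 of 100). As other splits called more for these 2, and fits of the compared groups alone 0, what they owe to chance or genotype stays open. For Th1 against Th0 in WT 5 of 100 splits called as many, 665 in the real split and 2125 in the highest other. Among the 14 fitted splits that part all pairs of these libraries, as the real one does, the highest other called 5.90 genes per 1000, against 30.4 in the real one; these are too few for a share under 0.05, and splits that called more keep pairs together. With 0 genes in the real split, all 40 splits call as many whatever the data, so the splits decide nothing for KO in Th0 (highest other 6) and Th1 (5), KI in Treg (850), KI against KO in Th0 (59) and Th1 (1), and the 4 differences between cultures (0, 22, 1 and 34). Splits that call several times the real number point to a structure among the libraries, not tested.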

Other observations

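The genes set out by library, and the comparisons of Myb and of seed-site genes by library number were chosen after the results by culture were seen. Effector genes differed widely between the 15 Treg libraries. Gzmb, which encodes granzyme B, a killing enzyme of cytotoxic cells, ran from 1.07 CPM in Treg WT 5 to 4416 CPM in Treg WT 4. Ifng ran from 0.623 CPM to 846 CPM in the same libraries, and Klf2, which keeps T cells quiescent, from 1.46 CPM in Treg WT 4 to 56.2 CPM in Treg KO 3. Treg WT 3, with 23.9 CPM of Cd8a, held 851 CPM of Gzmb, 78.7 CPM of Ifng and 4.93 CPM of Klf2. No test was made between these libraries.

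Camera called further lists between genotypes that had no member past the threshold over all genes. Between KI and KO in Th0, apoptosis genes had a median of 0.18, with 4 of 17 higher adjusted over the list alone (adjusted p = 7.98e-04 by camera, and adjusted p = 0.338 with an estimated correlation; adjusted p = 0.0202 by fry), and 1 without the libraries numbered WT 4, KO 2 and KI 3. In the same comparison the Th2 programme had a median of -1.47, with 3 of 13 lower adjusted over the list alone (adjusted p = 1.03e-04 by camera, and adjusted p = 0.810 with an estimated correlation), and 1 without these libraries, where the median was -0.93. In KO against WT in Th1, activation and inhibitory receptor genes had a median of -0.32, with 4 of 20 lower adjusted over the list alone (adjusted p = 0.0150 by camera, and adjusted p = 0.981 with an estimated correlation). In KI against WT in Th1, naive and quiescence genes had a median of 0.43 (adjusted p = 1.65e-04 by camera, and adjusted p = 0.679 with an estimated correlation). In KO against WT in Treg, cytokines and receptors linked to EAE had a median of -0.60 (adjusted p = 0.0224 by camera, and adjusted p = 0.372 with an estimated correlation; adjusted p = 0.0818 by fry, 0.0136 without these libraries).

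Myb may follow the genotype over all cultures, a hypothesis from the comparisons above. With each number of a genotype averaged over its cultures as 1 value, after removing the WT mean of each culture, Myb differed by 0.71 ± 0.10 (SE) for KO minus WT, -0.26 ± 0.10 for KI minus WT and -0.97 ± 0.10 for KI minus KO. Each difference had an exact two-sided permutation p of 0.00794, the smallest these 5 against 5 values can give, with no overlap between genotypes. Over all 21873 genes, limma's adjusted p for Myb was 0.163, 0.234 and 0.00430, so only the last passed, where Myb was the only gene called. The highest KI value, at -0.1334, lay just under the lowest WT value, at -0.1326, and the test was made on the data that raised the hypothesis. The labels do not say that a number marks an animal, and KI 2 has no Th0 library, so its value averages 2 cultures.

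The seed-site genes were compared by library number in the same way, as the mean log2 level relative to the weighted control genes. The difference was 0.0231 for KO minus WT (exact permutation p = 0.119), 0.0281 for KI minus WT (exact permutation p = 0.0397) and 0.00500 for KI minus KO (exact permutation p = 0.421). These p-values were not adjusted over the comparisons. KO and KI both lay above WT, unlike for Myb, where they lay on opposite sides of it. With unweighted control genes the differences by culture for KI minus WT were -0.0423, -0.0204 and -0.0291 in Th0, Th1 and Treg.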
